A study of Arabidopsis thaliana with 6 samples.

How the data were processed

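Gene expression was measured on 6 arrays of biotin-labelled total RNA from whole Arabidopsis thaliana seedlings of the line 35S::PLT2-GR. In this line the 35S promoter drives PLT2, an AP2-domain transcription factor of the PLETHORA family, fused to the ligand-binding part of the glucocorticoid receptor. Dexamethasone lets such a fusion enter the nucleus. Per the labels' protocols, seedlings aged 4 days were moved in batches of about 50 into flasks with 50 ml of liquid medium, kept there overnight, and given dexamethasone at 10 µM or the solvent DMSO (mock) for 6 h. Each group had 3 flasks, described in the labels as biological replicates. Flasks were treated at intervals of 5 minutes per the labels' protocols.

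The deposited values are log2 probe set values, 1 per array and probe set. RMA and limma 3.24.15 are named in the submitters' processing notes, without the role of each. The genome build and the level at which probes were summarised are not given in the sources used here. The medians of the 6 arrays nearly coincide, from 5.43 to 5.48, and no value is negative. The first quartiles were 3.05 to 3.08 in the mock arrays and 3.10 to 3.24 in the dexamethasone arrays. No per-gene centring was present. For arrays, the number of arrays limits the precision.

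The deposited table has 38408 probe sets. The platform's probe table pairs 17504 of them with a gene, 16746 with exactly 1 gene and 758 with several. The other 20904 probe sets are unnamed here and were left out of the main test. Of the probe sets with 1 gene, 16601 matched the RefSeq table of the TAIR10.1 assembly by gene ID and 145 did not. For 14824 of those matched the current symbol is only a locus code, and 1777 have another symbol. No coordinates are printed, because the build behind the probes is not given. The probe set of PLT2 itself was not analysed here. Hybridisation of 1 probe set with several similar genes was not checked.

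Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with default settings) as dexamethasone minus mock, two-sided, on the deposited log2 values without further normalization. P-values were adjusted by the Benjamini-Hochberg method over the 17504 probe sets with a gene, and the threshold was an adjusted p of 0.05. A fold is 2 raised to the log2 difference of the group means. SE is the moderated standard error, and SD is over the 3 arrays of a group. The same code was tested on simulated values for 17504 genes, of which 200 were given a known change. It recovered 10.3% of the genes with a log2 change of 0.5, 62.1% of those with 1 and 98.5% of those with 2, with 2 false calls. In the data 18.6% of probe sets passed, and the simulated noise was independent between genes. These shares therefore do not carry over directly to the real comparison.

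Before the data were examined, 17 gene lists with 275 members were fixed, together with the test, the alternatives and the rule for named genes. Of these members, 35 were paired with a probe set in the probe table and were kept, and they are called measured. Another member was left out because the table gave it a different symbol. The other members were not analysed here, and some of the unnamed probe sets may belong to them. Lists were tested with camera (preset correlation 0.01) on 16554 genes with 1 probe set each, the one with the highest mean, and beside it with an estimated correlation and with fry. Only the 10 lists with at least 2 measured members entered these tests, a minimum set after the coverage was seen. The rule named the 10 genes with the largest rise and the 10 with the largest fall among probe sets past the threshold that have 1 gene and whose groups do not overlap. From each list it added up to 3 members past the threshold with the largest change or, where none passed, the member with the smallest p, and it allowed any member of the PLETHORA family. PLT2 came first in the rule.

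A further 31 gene families and lists, the plastid genome among them, were drawn up after the data had been examined and after the largest changes were known, most by a shared symbol prefix and some by locus. They were tested with camera in the same way and adjusted over the 31. Genes named from them were chosen after their values were seen.

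Alternatives were the replicate number as a block, quantile normalization, median centring of each array, leaving out the 30% of probe sets with the lowest mean, eBayes with an intensity trend or robust, array weights, an adjusted p of 0.01, an added log2 change of at least 1, 1 probe set per gene, and leaving out each replicate in turn. A fit of all probe sets, named or not, was added after the data were seen.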

Results

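The data comprise 6 arrays of whole seedlings carrying 35S::PLT2-GR, 3 from mock-treated flasks and 3 from flasks with dexamethasone for 6 h. Each array gave a log2 value for 17504 probe sets with a gene. Pearson correlations across probe sets were 0.9804 to 0.9865 within groups and 0.9694 to 0.9752 between groups. The comparison asks which transcripts differ 6 h after the PLT2 fusion is activated.

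Dexamethasone-treated seedlings differed from mock seedlings in a large part of the measured transcripts. AT1G34047, which encodes a defensin-like protein, rose 26.3-fold (log2 change 4.72, SE 0.42). This value is approximate since its mock arrays differed (SD 0.94, n = 3). The change was 5.25 without mock replicate 1 and 4.37 without mock replicate 3. ATGSTF13, a phi-class glutathione S-transferase, rose 22.7-fold, and AT1G78520, with an X8 carbohydrate-binding domain, rose 19.9-fold. Among the falls, AT1G57590, a pectin acetylesterase gene, was 4.05-fold lower. The pectin methylesterase inhibitor gene AT4G25250 was 3.71-fold lower and the xyloglucan endotransglucosylase gene XTH33 was 3.31-fold lower. The order of the leading genes depended on single arrays: without mock replicate 2 ATGSTF13 (4.66) and without mock replicate 3 AT1G78520 (4.51) had a larger rise than AT1G34047, and without mock replicate 3 AT4G13440 (-2.03) and without dexamethasone replicate 1 AT1G05650 (-2.32) had a larger fall than AT1G57590.

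By limma, 3252 of 17504 probe sets (18.6%) passed the threshold, of which 1582 rose and 1670 fell. Changes of 2-fold or more were found for 324 probe sets that rose and 306 that fell. At 4-fold or more, 88 rose and 1 fell, and with 1 replicate left out 88 to 92 rose and 0 (without mock replicate 2) to 3 (without dexamethasone replicate 2) fell. The groups did not overlap for 6671 probe sets (38.1%), where chance gives 10%. Without mock replicate 1 the count past the threshold was 1724, without mock replicate 2 it was 2017 and without mock replicate 3 it was 2119. No dexamethasone-treated seedlings lacking the fusion are among these arrays, so effects of dexamethasone and of the fusion cannot be separated.

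**Figure D1:**
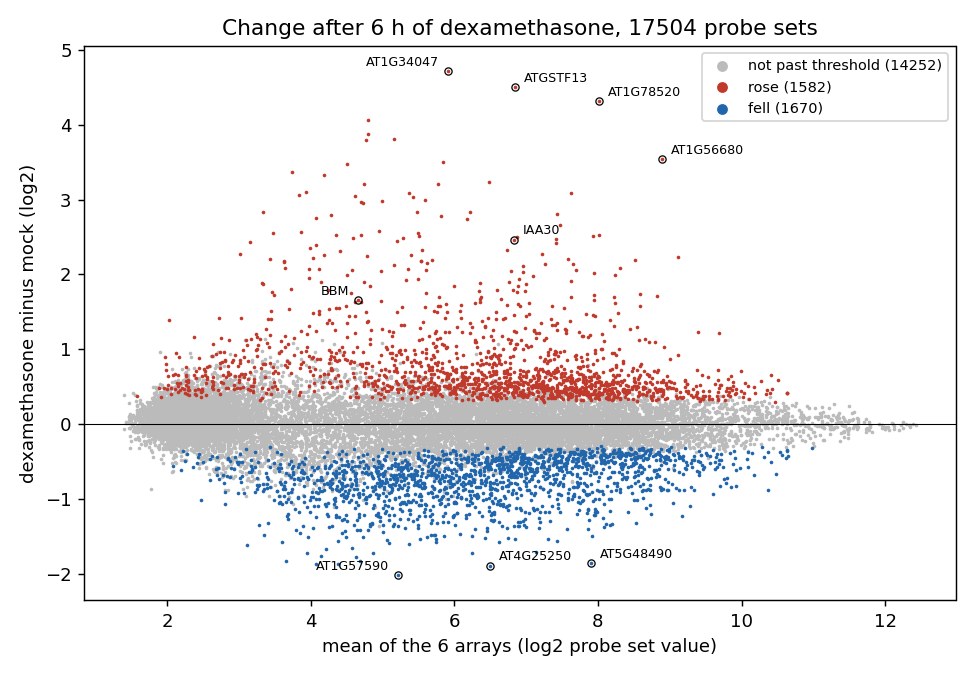
Each point is 1 probe set, placed by its mean log2 value over the 6 arrays (x axis) and by the log2 difference of dexamethasone minus mock (y axis), in red where it rose, blue where it fell and grey where it did not pass the threshold. Rises reach 4.72 while the largest fall is -2.02.

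Among the other large rises, AT2G40250 encodes an SGNH-type esterase and rose 14.8-fold, AT2G24560 encodes a GDSL lipase and rose by 3.81 on the log2 scale, and AT1G56680, of the chitinase family, rose 11.6-fold. AT2G05330, with a BTB/POZ domain, rose 16.7-fold. AT1G05577, known as SOSEKI1, rose 11.1-fold. AT3G04360 rose 13.9-fold and had the smallest adjusted p of these genes (1.761e-05), and AT5G50175 rose 11.4-fold. In mock seedlings AT2G05330, AT2G40250, AT3G04360 and AT1G05577 had mean log2 values of 2.77, 2.85, 2.87 and 2.76, under the first quartile of every array, and AT2G24560 had 3.26. Signal over background was not analysed here, so the folds of these genes are approximate.

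Among the other large falls, AT2G43880, of the pectin lyase-like superfamily, was 3.43-fold lower, and AT5G48490, which encodes a DIR1-like lipid-transfer protein, was 3.62-fold lower with SD 0.12 in mock and 0.13 in dexamethasone (n = 3 each). AT4G12500, of the lipid-transfer and albumin superfamily, was 3.38-fold lower. AT3G18450, with a PLAC8 domain, and AT5G62330 were both 3.66-fold lower, and AT4G13440, an EF-hand protein gene, was 3.56-fold lower, to a mean log2 value of 2.74 that makes its fold approximate too. AT1G05650, also pectin lyase-like, was 3.54-fold lower with an adjusted p of 0.032 and an SD of 1.02 among the dexamethasone arrays; its adjusted p was 0.0855 without mock replicate 1, 0.0853 without mock replicate 2, 0.0894 without mock replicate 3 and 0.0797 without dexamethasone replicate 2.

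**Figure D2:**
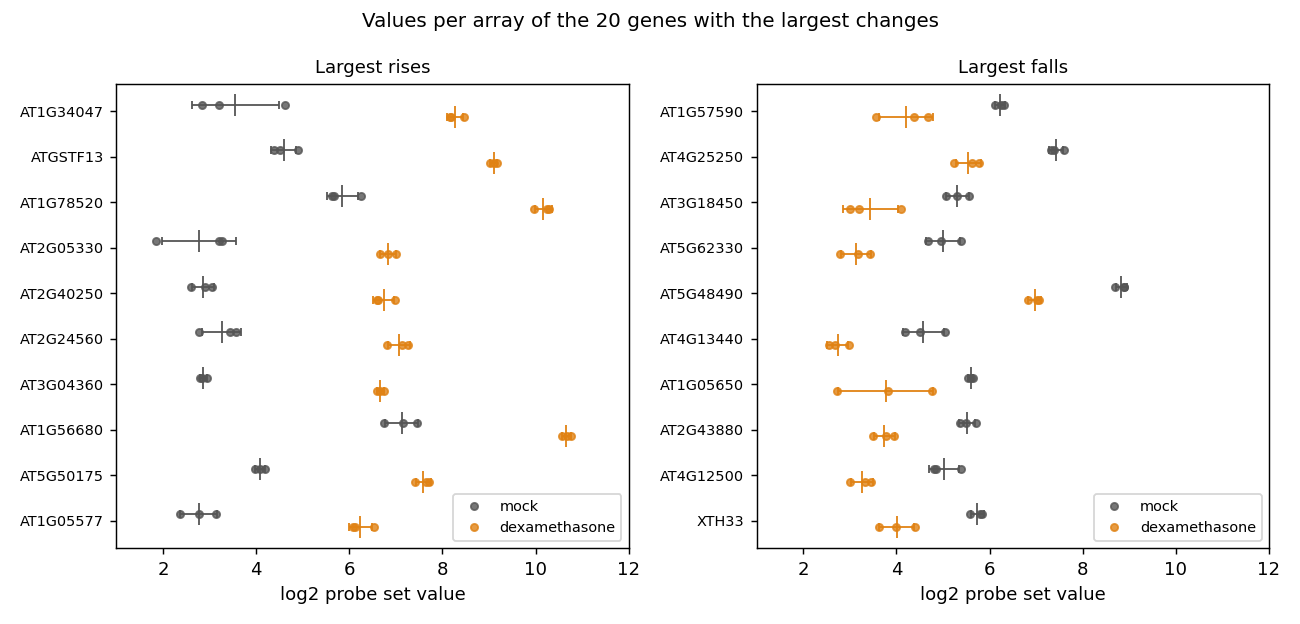
Log2 probe set values (x axis) of the 10 genes with the largest rise and the 10 with the largest fall (y axis), with a point per array, a vertical tick at the group mean and a bar of 1 SD to each side (n = 3). The genes were chosen among probe sets whose groups do not overlap, and AT1G05650 has the widest spread among its dexamethasone arrays, with an SD of 1.02.

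In the PLETHORA family, 2 of 8 members were measured. BBM, an AP2-domain gene that promotes embryo development, rose 3.14-fold (log2 change 1.65, SE 0.30, adjusted p 0.012), and AIL1 differed by 0.20 with an adjusted p of 0.45. PLT2 was not analysed here. Adjusted over the list alone, BBM rose and AIL1 did not pass. The camera test gave an adjusted p of 0.292 for this list.

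Auxin genes moved in both directions. Of 8 measured members of the auxin response list, 2 rose and 2 fell, and adjusted over the list alone 2 rose and 3 fell. IAA30, an Aux/IAA repressor gene, rose 5.53-fold (log2 change 2.47, SE 0.13), and GH3.3, for an auxin-conjugating enzyme, rose 1.47-fold with an adjusted p of 0.033. That call was lost in every fit that left out 1 replicate except the one without dexamethasone replicate 2, with adjusted p of 0.0901, 0.0822 and 0.0949 without mock replicates 1, 2 and 3, and 0.0521 and 0.0605 without dexamethasone replicates 1 and 3. IAA29 was 1.70-fold lower, and WES1 (also called GH3.5) was 1.64-fold lower. The adjusted p of WES1 was 0.0168, and 0.0619 without mock replicate 1 and 0.0502 without mock replicate 3. The list's mean change was 0.07 and its median -0.28, and camera placed it down with an adjusted p of 0.694. In auxin biosynthesis and transport, 1 of 3 measured members fell, and 2 fell when adjusted over the list alone. The flavin monooxygenase gene YUC2, for an enzyme of auxin synthesis, fell by 0.96 on the log2 scale (SE 0.15), while YUC6 had a change of -0.60 and an adjusted p of 0.053, or 0.0488 without dexamethasone replicate 2. The camera test gave an adjusted p of 0.292.

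Among cell cycle lists, SIM, an inhibitor of cyclin-dependent kinases that promotes endoreduplication, was the 1 measured member of 13 of its list and was 2.09-fold lower (log2 change -1.06, SE 0.13). In G1/S and DNA replication 2 of 22 members were measured and neither passed the threshold over all genes, while adjusted over the list alone both rose. PRL, the gene of the replication helicase subunit MCM7, had a log2 change of 0.28 and an adjusted p of 0.078 over all genes. ICU2, a DNA polymerase alpha gene, had a change of 0.29 and an adjusted p of 0.13, or 0.0482 without dexamethasone replicate 3. Camera gave an adjusted p of 0.292 for this list. None of the 3 measured Aurora kinase genes of the G2/M list passed, with AUR3 at 0.15, nor any adjusted over the list alone (camera adjusted p 0.801).

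The response regulator gene RR16, also called ARR16, was 1.80-fold lower and was the 1 of 2 measured cytokinin genes to pass, also when adjusted over the list alone (camera adjusted p 0.319). Of 4 measured root hair differentiation genes 2 fell, and adjusted over the list alone 2 fell and 1 rose. Those that fell were the root hair expansin genes EXPA18, 2.54-fold lower, and EXPA7, 2.34-fold lower. The camera test gave this list an adjusted p of 0.319. Of 4 measured root stem cell niche and root cap regulators none passed, over all genes or adjusted over the list alone, with AGL42 at a log2 change of 0.66 and an adjusted p of 0.17 (camera adjusted p 0.801).

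Of 2 measured photosynthesis genes, the Rubisco activase gene RCA fell by 0.32 on the log2 scale with an adjusted p of 0.0475, and LHCB4.1 had a change of -0.23 and an adjusted p of 0.12. Adjusted over the list alone both fell, and camera gave an adjusted p of 0.292. The call for RCA was lost in each fit that left out 1 replicate, with adjusted p from 0.0701 to 0.139. PDF1.2, CLV3 and GI, the named members of the stress, embryo and shoot meristem, and clock lists, did not pass, with changes of 0.26, 0.14 and 0.16. None of the 4 measured members of these lists passed, also when adjusted over the list alone, and camera gave the stress list an adjusted p of 0.801. None of the 10 tested lists passed with camera, by the preset or by an estimated correlation, and 3 passed with fry. The xylem, phloem, endodermal and ribosome biogenesis lists were not analysed here, since no member kept in them was named in the probe table.

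**Figure D3:**
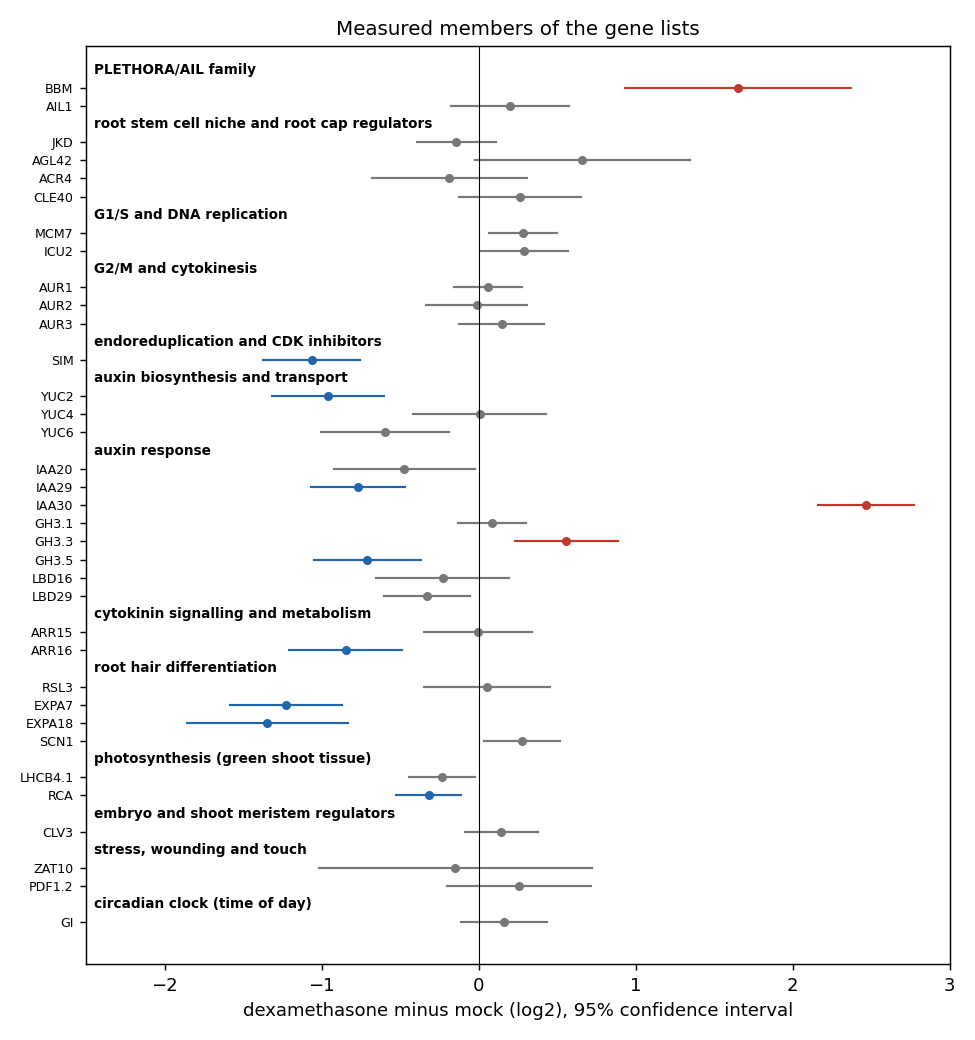
Log2 difference of dexamethasone minus mock (x axis) with its 95% confidence interval for each of the 35 measured members of the lists (y axis), in red where it rose, blue where it fell and grey where it did not pass the threshold. BBM, IAA30 and GH3.3 rose.

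The other gene families were drawn up after the data were examined. Of 64 measured class III peroxidase genes, which encode secreted haem enzymes of the cell wall, 30 fell and 2 rose. With 1 replicate left out, 24 (without mock replicate 1) to 31 (without dexamethasone replicate 3) fell. AT2G18980 was 2.90-fold lower and AT5G17820 was 2.63-fold lower, while Prx37 rose by 1.70 on the log2 scale. The list also holds AT4G26010, 2.98-fold lower, whose fall was already known when the list was drawn up. The camera adjusted p was 1.84e-07, and with an estimated correlation the adjusted p was 0.20. Of 10 measured genes in an added root hair list 8 fell, among them AT5G06630, 2.76-fold lower, and the peroxidase gene AT1G30870, 2.61-fold lower, and none rose. Without any 1 of mock replicates 1, 2 and 3 and dexamethasone replicate 1, 6 fell. The adjusted p of AT5G06630 was 0.0525, 0.054 and 0.0589 without mock replicates 1, 2 and 3, and 0.0577 without dexamethasone replicate 1. Camera gave the list an adjusted p of 1.81e-05, and the adjusted p was 0.237 with an estimated correlation. EXPA18 and EXPA7 belong to both root hair lists, so their falls are counted in each. They also carry the expansin symbol, and AT1G30870 is a peroxidase gene, so the counts of these families and lists are not independent.

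Of 24 trichome birefringence-like genes, a family linked to acetylation of wall polysaccharides, 8 fell and none rose, with TBL33 2.00-fold lower. Without any 1 of mock replicates 1, 2 and 3 and dexamethasone replicates 1 and 2, 5 fell. The adjusted p was 3.93e-04 by camera and 0.20 with an estimated correlation. Of 10 xyloglucan endotransglucosylase genes 5 fell and none rose, with XTH21 2.36-fold lower (adjusted p 0.0187 by camera and 0.237 with an estimated correlation), and 3 fell without mock replicate 1 or without mock replicate 3. XTH33, 3.31-fold lower, shares the symbol prefix of this family, and its fall was known when the families were drawn up. Of 55 UDP-glycosyltransferase genes 10 fell and 3 rose (adjusted p 0.0187 by camera and 0.219 with an estimated correlation). Of 24 beta-glucosidase genes 5 fell and none rose (camera adjusted p 0.0456, and adjusted p 0.237 with an estimated correlation), and 3 fell without mock replicate 1 or without dexamethasone replicate 2. Of 11 tau-class glutathione transferase genes 3 fell and none rose (camera adjusted p 0.0456, and adjusted p 0.476 with an estimated correlation). In all, 7 of the 31 families passed with the preset correlation and 16 with fry. None passed with an estimated correlation, where the lowest adjusted p was 0.1999. That estimate was below the preset 0.01 for trichome birefringence-like genes (-0.0337), beta-glucosidases (-0.0278), xyloglucan endotransglucosylases (-0.0141) and UDP-glycosyltransferases (-0.00956). This argues against a higher correlation between genes as the reason that these families did not pass. The estimate was above 0.01 for class III peroxidases (0.0322), tau glutathione transferases (0.092) and the added root hair list (0.203). With no family past it, not passing this test counts neither for nor against a fall of a family.

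**Figure D4:**
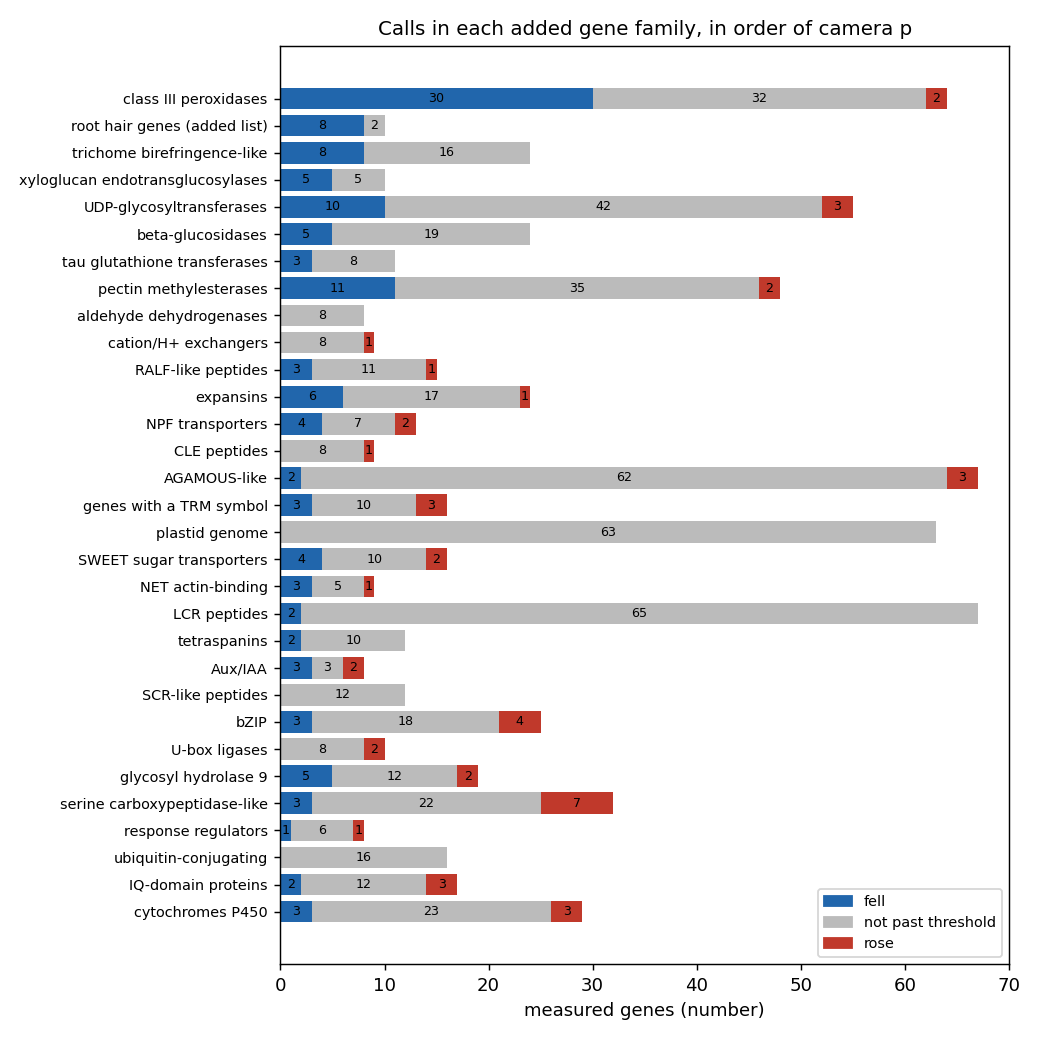
Number of measured genes (x axis) that fell (blue), did not pass (grey) or rose (red) in each of the 31 families and lists drawn up after the data were examined, ordered from the lowest camera p at the top. The class III peroxidases have the most falls, 30 of 64.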

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

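The count over other splits and the fit of all probe sets were chosen after the results were seen. Probe sets with no gene in the probe table were outside the main comparison, and 2454 of these 20904 passed the threshold in a fit of all probe sets, 1244 that rose and 1210 that fell. This is 11.7% of the unnamed probe sets, against 13.8% of the named ones in the same fit. By 2-fold or more, 379 unnamed probe sets rose and 283 fell. No biological explanation was tested for them.

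The 6 arrays can be parted into groups of 3 in 10 ways, too few for a share under 0.05. The real grouping gave 3252 probe sets past the threshold and was the 1 split with as many, and the highest count among the others was 0. Every other split mixes both treatments in each group, so a real difference widens its spread and lowers its count. That 0 is therefore not a level for chance.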

How the results depend on the processing

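The fit of all probe sets, every family test and the refits of genes named outside the rule were added after the data were seen. No probe set called in the main comparison changed direction in any of the refits listed here, but few of them could reverse one. All 3252 calls had groups that do not overlap, so leaving out 1 replicate or weighting arrays could not. The block, the trend, robust eBayes and the dim filter leave the log2 change as it is. Leaving out each replicate in turn gave 1724 to 2477 probe sets past the threshold, 828 to 1168 that rose and 896 to 1309 that fell; these fits have fewer arrays. The 3 lowest counts came without mock replicate 1 (1724), 2 (2017) and 3 (2119). An adjusted p of 0.01 left 1205, of which 574 rose and 631 fell, and a log2 change of at least 1 as well left 630, of which 324 rose and 306 fell. Over all probe sets, named or not, 2423 rose, since more were tested. In that fit only 2416 of the named probe sets passed, against 3252 in the main fit. The replicate block gave 2417, 2273 of them shared with the main fit without a block. Same-numbered arrays had correlations of deviations of -0.0316, 0.0153 and 0.0425, and not every array correlated best with its own number. A pairing by number was thus not seen, but 3 arrays per group cannot exclude one. Quantile normalization, median centring, the dim filter, robust eBayes, the trend and array weights gave 3153 (robust) to 4348 (trend), with 47.7% to 55.4% of calls rising, highest with median centring, and 1 probe set per gene gave 3101. Among named genes, RCA was not past the threshold with median centring (0.0895), the replicate block (0.101) or robust eBayes (0.0504), nor WES1 (0.051) or GH3.3 (0.0537) with the block; PRL passed with the dim filter (0.0399) and the trend (0.0291), YUC6 with quantile normalization (0.0474), the dim filter (0.0314), the trend (0.0158) and array weights (0.0446), and LHCB4.1 with the trend (0.0137). With fry in place of camera, 3 lists passed, G1/S and DNA replication (0.0425), root hair differentiation (0.0263) and photosynthesis (0.0235); fry does not compare a list with other genes. With an estimated correlation none of the 7 families passed: class III peroxidases 0.2, trichome birefringence-like 0.2, UDP-glycosyltransferases 0.219, the added root hair list 0.237, beta-glucosidases 0.237, xyloglucan endotransglucosylases 0.237 and tau glutathione transferases 0.476. No other family passed that test either, so it decides nothing about these. Leaving out dim probe sets moved UDP-glycosyltransferases to 0.0556, beta-glucosidases to 0.0928 and tau glutathione transferases to 0.0809, and quantile normalization moved the last to 0.058. Leaving out 1 replicate gave 0.0294 to 0.111 for beta-glucosidases and 0.0205 to 0.133 for tau glutathione transferases. Apart from the lower counts with fewer arrays, the cause was not tested. Signal over background was not analysed here, and values near the lower end of the range limit the folds of dim genes.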

Other observations

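The 4-fold tests were chosen after the result was seen, and the families after the data were examined. The tests of neighbouring genes were set before their values were seen. Those of root hair genes were set before the values of the list but after falls of other root hair genes, left out of it, were known. The comparison of root hair genes with JKD and ACR4 was not set beforehand. Other families held changes in both directions without passing camera. With fry, which does not compare a family with other genes, pectin methylesterases (adjusted p 0.0467), expansins (0.0326) and IQ-domain genes (0.0343) passed. So did RALF-like peptides (0.0427), AGAMOUS-like genes (0.0347), CLE peptides (0.0347), NET actin-binding genes (0.0354), cation/H+ exchangers (0.047) and U-box ligases (0.047). Of 9 measured CLE peptide genes only 1 was past the threshold, so a pass with fry can rest on few genes. Of 32 serine carboxypeptidase-like genes 7 rose and 3 fell (camera adjusted p 0.787), with scpl35 rising by 1.70 on the log2 scale and SCPL34 1.84-fold lower. Of 48 pectin methylesterase genes 11 fell and 2 rose (camera adjusted p 0.0676), and 1 rose in each fit that left out 1 replicate except that without dexamethasone replicate 1. AT1G05310 was 3.17-fold lower, while AT1G02810 rose by 2.47, and both changes were known when this family was drawn up. Of 24 expansin genes 6 fell and 1 rose (camera adjusted p 0.269), and EXPA8 was 2.17-fold lower; 0 rose without mock replicate 2 or 3, and 2 rose without dexamethasone replicate 2. In the Aux/IAA family 2 of 8 measured genes rose, IAA30 and IAA33, and 3 fell (camera adjusted p 0.709), or 1 without mock replicate 1, mock replicate 3 or dexamethasone replicate 1. Of 25 bZIP genes 4 rose and 3 fell (camera adjusted p 0.783); the flowering regulator FD rose by 1.15 and BZIP61 was 2.54-fold lower. Among 17 IQ-domain genes 3 rose and 2 fell (camera adjusted p 0.802), and IQD16 rose by 1.94; 1 fell in each fit that left out 1 replicate and with quantile normalization.

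Rises of 4-fold or more outnumbered falls, 88 to 1 (0 to 3 falls with 1 replicate left out), and over all deposited probe sets, named or not, 146 to 9 (94.2% rises). An excess of rises at 2-fold or more was looked for first and was not there at the main scaling (324 and 306), while median centring gave 356 and 265 and all deposited probe sets 691 and 566, and the 4-fold bound was chosen after the counts were seen. For a floor of the array that limits falls, probe sets with a mean log2 value of 5.49 or more were counted. There 41 rose and 0 fell (100%, exact 95% interval 91.4 to 100, which takes genes as independent). That mean is over both groups, so it admits genes dim in mock with little room for a 4-fold fall. Examples are AT1G34047 (3.55 in mock, 8.27 in dexamethasone) and AT5G50175 (4.08 and 7.59). With a mean of 7.25 or more, 17 rose and 0 fell. Probe sets were not chosen by their mock level, so a floor stays open as part of the cause. Unequal centring of the arrays is argued against only by the small size of the shift, 0.0399 on the log2 scale with median centring. Median centring took all rises from 1582 to 1833 and left 91 rises and 0 falls of 4-fold (100%, 96 to 100). With so small a shift that 4-fold count could hardly have come out otherwise, so it adds no further support. A shift common to most genes that the deposited normalization took out, and slow loss of RNA already present, which may limit falls within 6 h, were not tested and stay open.

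Neighbouring genes changed together slightly more than by chance order. Across 10256 pairs of adjacent genes, which are not independent replicates, the correlation of log2 changes was 0.0907, against -0.0321 to 0.0279 in 1000 shuffles, and 135 pairs fell together where chance gives 95.2 and 103 rose together where chance gives 87.4. Among pairs more than 1000 bases apart it was 0.0889, above the highest shuffle (0.043), which argues against overlapping or abutting transcripts as the whole cause; there 67 pairs fell together (39.3 by chance) and 38 rose together (36.1 by chance). For genes 2, 5 and 10 apart the correlations were 0.0141, 0.0221 and 0.0206, each within its shuffled range. There were 18 runs of 3 or more adjacent genes called the same way, 9 of each direction. No count of runs by chance is given here. Without probe sequences it cannot be told apart whether probes read similar tandem copies. Shared regulation of neighbours is a hypothesis that stays open.

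Root hair genes fell in the added list, 8 of 10, or 6 without any 1 of mock replicates 1, 2 and 3 and dexamethasone replicate 1. The outcome set beforehand as counting against a fall of the list as a set, an adjusted p of 0.05 or more with an estimated correlation, was met (0.2371), but that test passed none of the 31 families (lowest 0.1999), so it separates neither reading; fry, which does not compare the list with other genes, gave an adjusted p of 0.006265, and a fall of the set beyond that of other genes is not established. The outcome set beforehand against a smaller share of root cells, a mean change of the 63 plastid genes at or under 0, was also met (-0.02554), but its interval, -0.185 to 0.134, spans 0, and both tests were read as undecided only after the values were seen. The 2 measured photosynthesis genes, which a smaller root share would raise, lay below 0, RCA at -0.32 (95% interval -0.53 to -0.11) and LHCB4.1 at -0.23 (-0.44 to -0.02), which goes against it, and RCA stayed between -0.36 and -0.28 with 1 replicate left out although its call was lost there, but these are only 2 genes and a direct effect of the treatment on them was not tested. Among root stem cell niche and root cap regulators, JKD changed by -0.14 (95% interval -0.39 to 0.11) and ACR4 by -0.19 (-0.68 to 0.31). Both intervals lie above those of EXPA18 (-1.86 to -0.83) and EXPA7 (-1.59 to -0.87). For EXPA18 and EXPA7 this goes against an equal loss of all root cells as the whole cause only if JKD and ACR4 follow the share of root cells. The comparison was not among those set beforehand. A direct effect on JKD and ACR4, or their expression outside the root, was not tested. AGL42 (0.66) and CLE40 (0.26) were dim. A smaller share of root cells as part of the cause and a response of root hair cells may each apply and cannot be told apart here.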
